A study of Escherichia coli with 7 samples.

How the data were processed

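The study measured ribosome footprints in 4 libraries and tRNAs in 3 libraries of Escherichia coli MG1655. Per the labels' protocols, footprints were made by MNase digestion and ribosome pelleting, and both kinds of library went through linker ligation, rRNA depletion, reverse transcription, circularization and PCR. tRNAs were deacylated before linker ligation. MNase cuts with a sequence preference, PCR can copy one molecule several times, and no molecular identifiers are named, so counts are reads, not molecules. CASAVA 1.8 and Bowtie2 2.1.0 are named in the submitters' processing notes, with no role given. The genome build, the annotation, the read filters, the counting rule and the use of strand are not given in the sources used here.

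Each file deposited by the authors holds a feature name, a length and a whole-number read count, with no header. The counts are raw: totals differ between libraries and no normalization was seen in them. The length column equals the RefSeq gene length divided by 3 for 4076 of the 4283 matched genes, so it was read as codons for genes and as length over 3 for tRNAs. The footprint files hold 4294 genes by locus tag. Of these, 4283 matched a locus tag of the RefSeq annotation of assembly ASM584v2, which was used only for names: 4152 protein-coding genes and 131 pseudogenes. The other 11 kept their locus tags. The files hold no row for a tRNA, rRNA or small RNA gene of the list of non-translated RNAs, so that list has 0 measured members and ssrA is not reported. The tRNA files hold 50 rows, of which 1 has an undetermined anticodon. That row held 326 reads in the input (0.00621%) and 0 in both RNC libraries. It is part of the input total of 5252209 counts given below, but stayed out of the totals used for shares and out of the main test.

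Groups and replicate numbers were taken from the sample titles. Footprint counts of the high-salt group (n = 2) were compared with those of the Cm group (n = 2) by edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at its defaults (3434 genes kept) and the quasi-likelihood test, two-sided, with an adjusted p threshold of 0.05. The fit without the replicate number as a term was chosen before the data were examined and has 2 residual degrees of freedom. The SE of a fold change is the log2 fold change divided by the square root of the F statistic. CPM are counts per 1000000 gene counts of the library. Gene lists were tested with camera (limma 3.58.1) where at least 5 members were tested. tRNA counts of RNC (n = 2) were compared with the input (1 library) by the same edgeR test, scaled to the total tRNA count so that a fold is a ratio of shares, for single species and for sums per amino acid. This fit has 1 residual degree of freedom.

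Named genes followed a rule set before the data were examined. It took up to 10 called genes per direction with a mean of at least 10 CPM and non-overlapping groups (where none was called, the 5 with the smallest p among such genes), the 10 genes with the highest mean CPM, 2 to 4 abundant members of each list, and secM and tnaC. For tRNAs it took up to 10 called species per direction and the 5 largest shares in each group. Other species and amino acids were named after their values were seen. The lists covered ribosomal proteins, translation factors, ribosome assembly and hibernation factors, aminoacyl-tRNA synthetases, leader and arrest peptides, protein export, respiration, transporters, outer membrane proteins, carbon metabolism, heat shock, cold shock, flagella, amino acid biosynthesis, RpoS-dependent genes, transcription, small peptides and non-translated RNAs. Some genes belong to more than one list, such as raiA, which was counted among cold shock and hibernation genes.

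Because libraries with the same number were more alike than libraries of one group, the ratio of high salt to Cm was also computed within each number from shares of counts, with 0.5 added to each count. Its interval is the 95% Clopper-Pearson interval of the high-salt count among the counts of both libraries. Replicates were compared before averaging: the chi-square per gene was 453 for the Cm libraries and 411 for the high-salt libraries, and 96.0 per species for the RNC libraries, so no library looked like a second copy of another of its group. Between the groups, the chi-square per gene was 9.44 for the number-1 libraries and 9.92 for the number-2 libraries, which also differed.

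The tests were tested on simulated data. For the footprint comparison, 200 of 3434 genes were changed at the real means, library sizes and spread, with the spread drawn separately for each library. The test recovered 4% of 2-fold, 48% of 4-fold, 78% of 8-fold and 96% of 16-fold changes, with 2 false calls. With the spread left after the replicate number is taken out, it recovered 92% of 2-fold changes, with 12 false calls. For the 49 tRNA species, 100 simulations without any change gave a call in 16, more often than the threshold of 0.05 implies. In 100 simulations with the shares of 10 species changed, 70.2% of the changes of at least 2-fold were recovered (463 of 660). The 45 calls of unchanged species made up 8.86% of the false and these recovered calls together, with calls of smaller changes not counted. The shares of the 10 species were set to 4-fold up or down and then rescaled to keep the total share of the 10. The 70.2% is therefore not the recovery of 2-fold changes. In simulations where the total share of the changed species was free to move, 22.8% of 2-fold (91 of 400), 63.3% of 4-fold (190 of 300) and 74% of 8-fold changes (222 of 300) were recovered, with 156 false calls. With the spread left after the replicate number is taken out and ribosomal proteins moved by 0.5 on the log2 scale, the list test called that list and 0 others of 17. The list test was not simulated with the spread of the main fit, so its recovery there is not known.

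Alternatives planned before the data were examined were RLE size factors, total-count scaling, TMM for tRNAs, no filter, DESeq2 1.42.0, a minimum log2 fold change of 1, a replicate block, fry, an estimated correlation and leaving out each library. Summing tRNA species of one anticodon was added after seeing the data. Ratios, resampling and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.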

Results

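Ribosome footprints and tRNAs were sequenced from Escherichia coli MG1655, a standard wild-type laboratory strain. The 4 ribosome profiling libraries came from ribosomes pelleted after digestion with micrococcal nuclease (MNase). Of these, 2 were labelled chloramphenicol (Cm) and 2 were labelled chloramphenicol with a high-salt wash. Chloramphenicol is an antibiotic that binds the large ribosomal subunit and blocks peptide bond formation. The 3 tRNA-seq libraries were 2 labelled RNC, an abbreviation that the labels do not expand, and 1 labelled input. The footprint libraries held 15618742 and 8937650 gene counts in the Cm group and 10427959 and 10296299 in the high-salt group. The RNC libraries held 35593 and 115113 tRNA counts and the input held 5252209. The labels do not say whether libraries of one group came from separate cultures, so the p-values measure only the spread between these libraries.

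The 2 libraries of one group differed more than the 2 libraries that share a replicate number. Footprint levels are given as CPM, the count per 1000000 gene counts of the library. Over 1989 genes with a mean of at least 200 counts, Pearson's r of log2(CPM + 1) was 0.915 between the Cm libraries and 0.914 between the high-salt libraries. It was 0.998 between the libraries numbered 1 and 0.997 between the libraries numbered 2. These correlations are across genes, which are not independent replicates. cspA, the major cold shock protein, was at 44672 CPM in Cm replicate 1 and 10663 CPM in Cm replicate 2. tnaA, the tryptophanase gene, was at 6891 and 18025 CPM in the same libraries. For this reason the change after the high-salt wash is given below over all 4 libraries and also within each replicate number, with the groups taken as labelled.

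The first comparison asked whether washing the ribosomes with high salt changed which open reading frames (ORFs) the footprints came from. Most of the abundant genes took nearly the same share of the counts with and without the wash, while several very short ORFs had lower shares in the high-salt library of both replicate numbers, though no gene passed the test. ypfM, a small ORF of 20 codons, was at 246 ± 7.21 CPM in Cm and 105 ± 15.8 CPM after the wash (SD, n = 2 each), a log2 fold change of -1.23 ± 0.27 (SE). hisL and pheL, the leader peptides of the histidine and phenylalanine biosynthesis operons, had log2 fold changes of -0.67 ± 0.26 and -0.58 ± 0.30 (SE). hisL was at 54.5 ± 0.929 CPM in Cm and 34.1 ± 3.38 CPM after the wash, and pheL was at 349 ± 5.68 and 232 ± 61.8 CPM (SD, n = 2 each). Of 3434 genes tested, 0 were called higher and 0 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.99996), in a fit without the replicate number as a term, so that the difference between the numbers counted as spread within each group. At an unadjusted p below 0.05 edgeR gave 1 gene, ypfM. DESeq2 also called 0 genes, with 1 at an unadjusted p below 0.05. With 3434 genes tested, a threshold of 0.05 would pass more than 1 by chance alone. The p-values of this fit thus ran high, and the 0 calls do not show that no gene changed. Calls with the replicate number as a block are given in the part on processing.

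Within the replicate numbers the direction of these ORFs was shared, but this is no separate support. They were named from genes with non-overlapping groups, for which the direction in both numbers is fixed in advance. For ypfM the log2 ratio of high salt to Cm was -1.12 in the number-1 libraries (95% Clopper-Pearson counting interval -1.21 to -1.02) and -1.37 in the number-2 libraries (-1.48 to -1.26). For hisL the log2 ratios were -0.76 (-0.95 to -0.58) and -0.59 (-0.79 to -0.40), and for pheL they were -0.36 (-0.42 to -0.29) and -0.87 (-0.96 to -0.79). tnaC, the leader ORF of the tryptophanase operon on which ribosomes arrest when tryptophan is abundant, had log2 ratios of 0.62 (0.58 to 0.65) and 0.10 (0.07 to 0.14). secM, whose arrest sequence controls the secretion ATPase gene secA, had log2 ratios of 0.44 (0.36 to 0.53) and 0.14 (0.0023 to 0.28). Over the 4 libraries the log2 fold change was 0.32 ± 0.37 (SE) for tnaC and 0.35 ± 0.55 (SE) for secM, neither past the threshold. The intervals cover counting error only, and each ratio compares 1 library with 1 library.

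**Figure D1:**
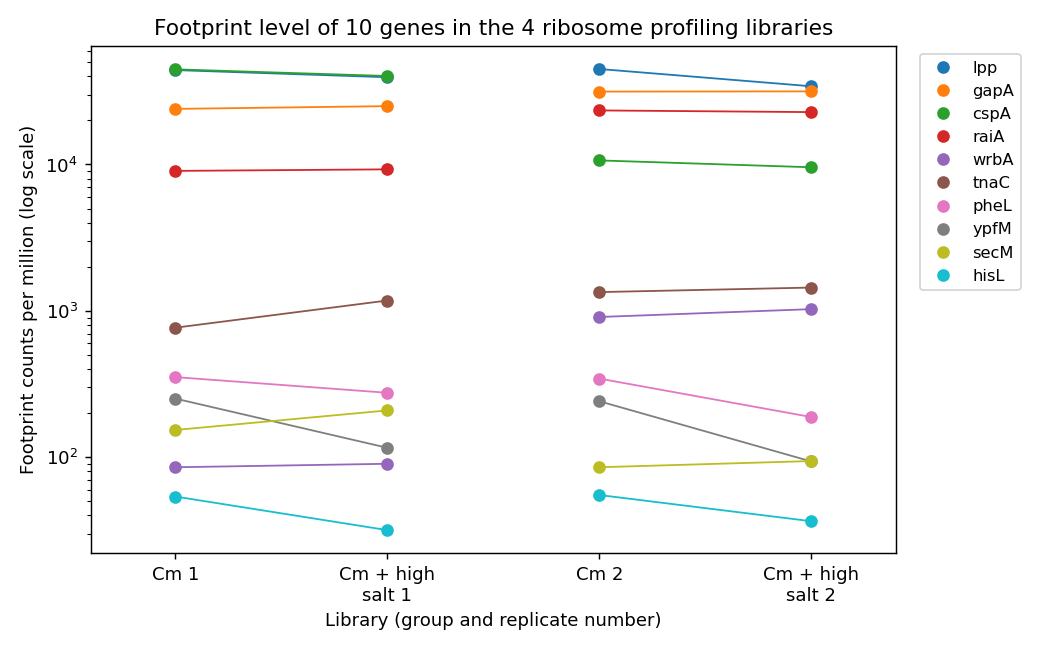
Footprint level of 10 genes in CPM (log axis) in each of the 4 ribosome profiling libraries, with lines joining the Cm and high-salt libraries of one replicate number. ypfM, hisL and pheL, named from genes with non-overlapping groups, are lower in the high-salt library of both numbers. tnaC and secM are higher, while cspA differs between the numbers (44672 and 10663 CPM in the Cm libraries).

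The other genes with the smallest p in each direction had smaller fold changes than ypfM. ftsB, a cell division gene, and yfjH had log2 fold changes of -0.52 ± 0.28 and -0.46 ± 0.28 (SE). Among genes with higher values after the wash, umpG was at 0.48 ± 0.33, yfcF at 0.47 ± 0.31, yhfK at 0.41 ± 0.28, yjcO at 0.38 ± 0.32 and hypF at 0.34 ± 0.29 (log2 fold change ± SE). None of these 7 genes passed the threshold. The highest mean CPM over the 4 libraries was that of lpp, the major outer membrane lipoprotein, while cspA was above it in both number-1 libraries. lpp was at 44552 ± 540 CPM in Cm and 36853 ± 3696 CPM after the wash. The log2 fold change of lpp was -0.27 ± 0.25 (SE), with within-number log2 ratios of -0.16 and -0.39. gapA, the glycolytic glyceraldehyde-3-phosphate dehydrogenase, and the porin genes ompC and ompA had log2 fold changes of 0.03 ± 0.30, 0.03 ± 0.30 and 0.01 ± 0.25 (SE). The elongation factor Tu genes tufA and tufB were at 0.07 ± 0.26 and 0.09 ± 0.25 (SE). The 2 genes are nearly identical, so the split of reads between them is uncertain. The genes cspA, cspE, raiA and tnaA had log2 fold changes of -0.14, -0.14, -0.01 and 0.06, with SEs of 1.01, 0.76, 0.69 and 0.73. These SEs include the difference between the replicate numbers. Within the numbers the log2 ratios of high salt to Cm were -0.15 and -0.16 for cspA and -0.19 and -0.04 for cspE. They were 0.04 and -0.04 for raiA and 0.01 and 0.08 for tnaA, each from 1 library against 1 library. The median SE over all tested genes was 0.42. In data simulated with this spread, which includes the difference between the replicate numbers, the test recovered 4% of 2-fold changes, 48% of 4-fold changes and 78% of 8-fold changes. The simulation drew the spread separately for each library, whereas in these data same-numbered libraries largely shared it. Most 2-fold changes were thus missed in the simulation, and the recovery in these libraries is not known.

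Gene lists fixed before the data were examined were tested with camera at a preset inter-gene correlation of 0.01. None of the 17 lists passed. With an estimated correlation every list had the same adjusted p of 0.945 (camera), so that setting could not tell the lists apart. In every list, 0 members were called over all genes and 0 were called when adjusted over the list alone. The lowest adjusted p was 0.127 (adjusted p = 0.945 with an estimated correlation), for small hydrophobic and toxin peptides. Of the 12 tested members of that list, 8 had a negative and 4 a positive log2 fold change, with a median of -0.10. Its most abundant members were acrZ, ypfM, cydX and mgtS, at log2 fold changes of 0.06, -1.23, -0.08 and -0.35. Leader and arrest peptides had 10 tested members, 4 with negative and 6 with positive values (adjusted p = 0.444). In that list the mean, -0.06, and the test pointed down while the median, 0.05, was positive.

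The remaining lists held medians between -0.02 and 0.06. Central carbon metabolism had 45 of 53 members with positive values and a median log2 fold change of 0.05 (adjusted p = 0.231), among them the fermentation genes pflB at 0.09 ± 0.25 and adhE at 0.08 ± 0.72 (SE). Aminoacyl-tRNA synthetases had 19 of 23 members with positive values and a median of 0.06 (adjusted p = 0.444), with serS at 0.07 and thrS at 0.01. Amino acid biosynthesis had 64 of 95 members with positive values and a median of 0.04 (adjusted p = 0.231), with glnA at 0.09 and glyA at 0.14. Ribosomal proteins were split, 29 positive and 26 negative, with a median log2 fold change of 0.014, a mean of -0.00038 and a test that pointed up (adjusted p = 0.841). rpsA was at 0.10 ± 0.64 and rplL at 0.08 ± 0.58 (log2 fold change ± SE). Translation factors had 14 positive and 7 negative values (adjusted p = 0.699), with fusA at 0.05 and tsf at -0.10. Cold shock proteins had 9 positive and 14 negative values (adjusted p = 0.841), with cspC at -0.19 ± 0.33 (SE). The adjusted p was also 0.841 for 5 more lists. Inner membrane transporters had 42 positive and 39 negative values, with the glycerol kinase gene glpK at 0.11. Outer membrane and periplasmic proteins had 19 and 21, with the maltose-binding protein gene malE at 0.06. RpoS-dependent stress genes had 19 and 19, with dps at -0.05 and rpoS at -0.03. Protein export and membrane insertion had 19 and 12, with secB at -0.03 and secA at -0.02, and ribosome assembly and hibernation factors had 11 and 14, with deaD at 0.02. In the transporter list the median, 0.0040, and the test were positive and the mean, -0.0045, negative. In the assembly list the median, -0.014, and the mean, -0.0099, were negative and the test pointed up.

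The adjusted p was 0.699 for the respiratory chain and ATP synthase, with 24 positive and 15 negative values, among them the ATP synthase genes atpD at 0.08 and atpA at 0.07. It was also 0.699 for the transcription machinery and nucleoid proteins, with 15 and 14, among them the nucleoid protein gene hns at -0.15 and rpoC at 0.02. Flagella and chemotaxis had 18 and 16, with the hook gene flgE at 0.24 and flgM at -0.19 (adjusted p = 0.699). In the flagella list the median, 0.03, was positive while the mean, -0.07, and the test pointed down. Heat shock proteins and proteases had 9 and 18, with the chaperone genes groL at -0.02 and dnaK at 0.04 (adjusted p = 0.895).

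**Figure D2:**
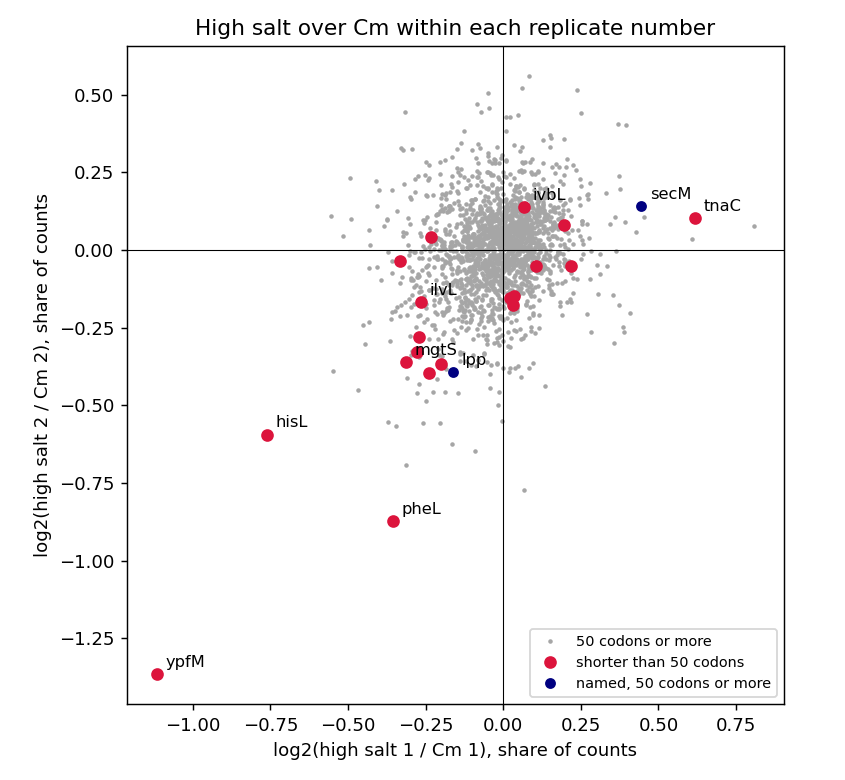
Log2 ratio of high salt to Cm in the number-1 libraries (x axis) and in the number-2 libraries (y axis), as shares of counts, for 1989 genes with a mean of at least 200 counts. ORFs shorter than 50 codons are red, and the longer named genes lpp and secM dark blue. ypfM, hisL and pheL lie at the lower left, and tnaC and secM on the upper right.

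The second comparison set the tRNAs in the RNC libraries against those in the input. Of 49 tRNA species tested, 4 were called higher as a share of tRNA counts, 8 were called lower and 37 did not pass the threshold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The input is 1 library, assumed to vary like the RNC libraries, and 16 of 100 simulations without any change also gave a call, so these calls are tentative. The species called higher were 2 threonine tRNAs with the anticodon CGT, the asparagine tRNA with GTT and the proline tRNA with CGG (anticodons as in the gene sequence). trna5-ThrCGT took 1.53% ± 0.118 of the counts in RNC (SD, n = 2) and 0.279% in the input, a 5.49-fold higher share (log2 fold change 2.46 ± 0.34, SE). trna6-ThrCGT took 1.29% ± 0.163 and 0.293%, a 4.40-fold higher share. trna18-AsnGTT took 8.79% ± 2.18 and 1.62%, a 5.44-fold higher share (log2 fold change 2.44 ± 0.57, SE). trna56-ProCGG took 6.54% ± 0.495 and 1.78%, a 3.68-fold higher share. The adjusted p was 0.0453 for both threonine species and 0.0483 for trna18-AsnGTT and trna56-ProCGG (edgeR).

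Of the 8 species called lower, 3 were serine, 3 leucine, 1 threonine and 1 alanine tRNAs. trna73-SerCGA took 0.073% ± 0.036 of the counts in RNC and 0.411% in the input, which was 5.37-fold lower (log2 fold change -2.42 ± 0.55, SE). Its log2 ratio to the input was -3.11 without RNC replicate 2 and -2.07 without RNC replicate 1. trna63-SerGCT and trna79-SerGGA were 3.17-fold and 3.12-fold lower. trna83-LeuTAG, trna38-LeuCAG and trna53-LeuCAG were 3.74-fold, 2.96-fold and 2.45-fold lower. trna70-AlaGGC took 0.705% ± 0.175 in RNC and 2.33% in the input (3.31-fold lower), and trna59-ThrGGT took 1.58% ± 0.011 and 4.28% (2.71-fold lower). Both RNC libraries lay on the same side of the input for each of the 12 species called. The 95% Clopper-Pearson interval of the input share, which covers counting error only, was 0.406% to 0.417% for trna73-SerCGA and 1.61% to 1.63% for trna18-AsnGTT.

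**Figure D3:**
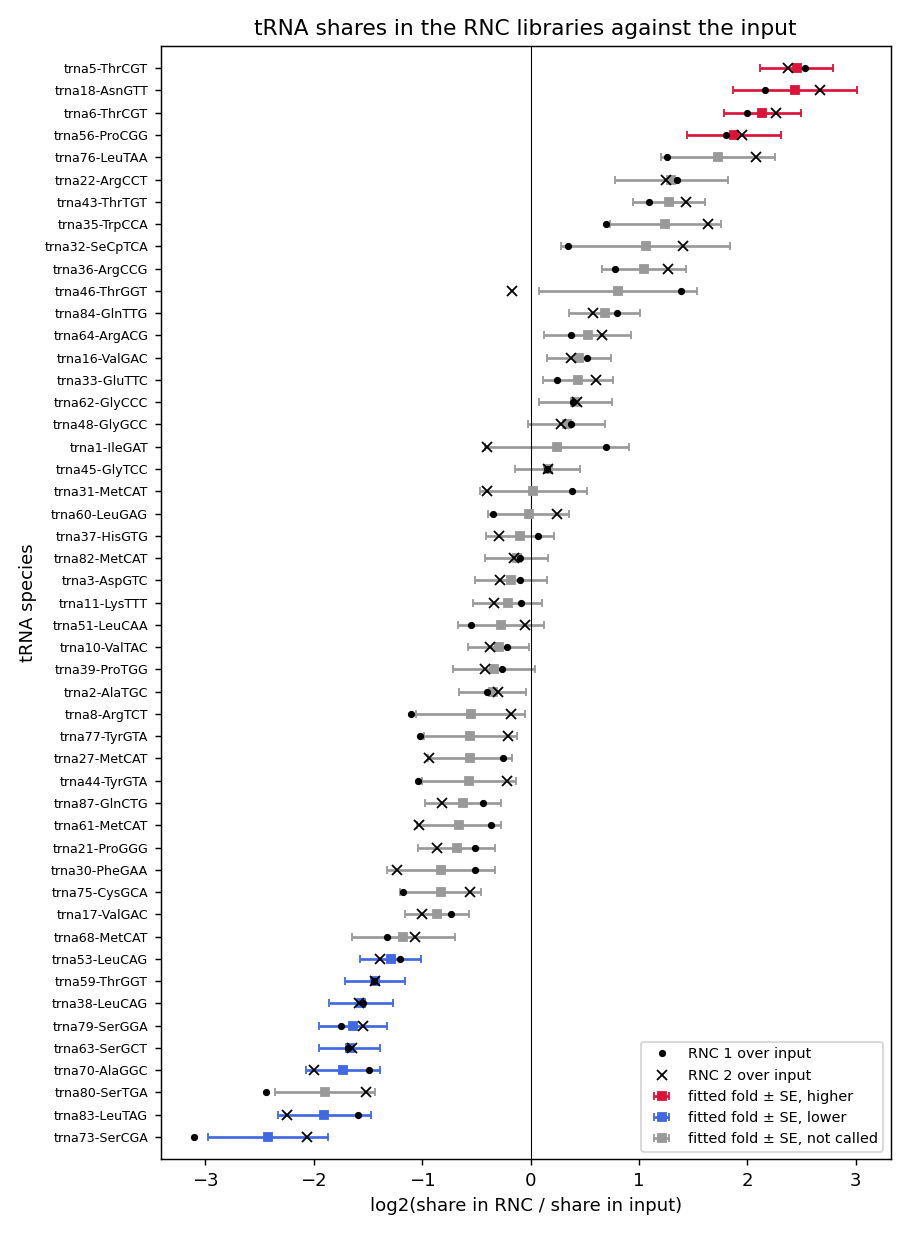
Log2 ratio of the share of tRNA counts in RNC to that in the input for the 49 tRNA species tested. Squares are fitted folds with their SE (red higher, blue lower, grey not past the threshold), and dots and crosses are RNC replicates 1 and 2. Threonine CGT, asparagine GTT and proline CGG species stand highest, and serine, leucine TAG and alanine GGC species lowest.

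Every adjusted p of a called species lay between 0.0453 and 0.0483 in edgeR. With TMM or RLE scaling in place of the total count, 0 species were called in either direction by edgeR (smallest adjusted p = 0.0577 and 0.0689), and DESeq2 called 9 higher and 9 lower. RLE scaling raised the median log2 fold change over the 49 species by 0.19, and the 12 species had the same direction under TMM, RLE and DESeq2.

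Isoacceptors of one amino acid differed in their values. Among the leucine tRNAs, trna76-LeuTAA took 4.87% ± 1.92 of the counts in RNC and 1.47% in the input without passing the threshold (edgeR adjusted p = 0.0913), while 3 other leucine species were called lower. Among the proline tRNAs, CGG was called higher, whereas trna39-ProTGG took 4.30% ± 0.337 and 5.43% and trna21-ProGGG 0.451% ± 0.077 and 0.720%. The 2 threonine species with the anticodon GGT were separated in the files. trna59-ThrGGT was called lower, and trna46-ThrGGT took 4.13% in RNC replicate 1, 1.40% in RNC replicate 2 and 1.57% in the input. The serine species trna80-SerTGA, at 0.471% ± 0.205 and 1.77%, just missed the threshold (edgeR adjusted p = 0.0511). Species with nearly identical sequences can share reads, so the split within ThrCGT, ThrGGT, LeuCAG, TyrGTA and MetCAT species is uncertain. With species of one anticodon summed, LeuCAG was not called at a log2 fold change of -1.45, close to those of its single species at -1.29 and -1.56 (edgeR adjusted p = 0.0646). ThrGGT was not called at -0.43 (edgeR adjusted p = 0.601). In that test LeuTAA, with 0.0389, and ThrTGT, with 0.0241, were called higher, and SerTGA, with 0.0108, was called lower (edgeR adjusted p).

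The most abundant species in RNC by mean share were trna18-AsnGTT (8.79%), trna1-IleGAT (7.20% ± 3.67), trna56-ProCGG (6.54%), trna64-ArgACG (5.16% ± 0.722) and trna76-LeuTAA (4.87%). In the input they were trna30-PheGAA (7.69%), trna1-IleGAT (6.06%), trna39-ProTGG (5.43%), trna38-LeuCAG (5.25%) and trna59-ThrGGT (4.28%). The 5 tRNAs with the anticodon CAT are all named MetCAT, so the initiator tRNA could not be told from the others and is not reported as such. Grouped by the chemistry of the amino acid, 4 of the 17 species for aliphatic amino acids and methionine were called lower and 0 higher. Of the 13 species for small and polar amino acids, 3 were called higher and 4 lower. Among the 6 glycine and proline species 1 was called higher, and 0 of 4 aromatic, 0 of 2 acidic and 0 of 6 basic species passed the threshold.

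Summed per amino acid, asparagine was the only one of 21 to pass the threshold, at 1.62% of the counts in the 1 input library and 8.79% ± 2.18 in RNC (SD, n = 2, edgeR adjusted p = 0.0165). This test too assumes that the input varies like the RNC libraries. Serine did not pass the threshold at 5.50% in the input and 1.59% ± 0.292 in RNC (log2 fold change -1.78 ± 0.45, SE, edgeR adjusted p = 0.0692), and passed it with TMM scaling (adjusted p = 0.00838), RLE scaling (adjusted p = 0.0155) and DESeq2 (adjusted p = 4.55e-04) but not without the filter (edgeR adjusted p = 0.0719). Tryptophan was at 1.36% in the input and 3.22% ± 1.43 in RNC, which did not pass the threshold by edgeR (adjusted p = 0.330) and passed it by DESeq2 (adjusted p = 0.0370). Phenylalanine was at 7.69% in the input and at 5.40% and 3.27% in RNC replicates 1 and 2, also not past it. At an unadjusted p below 0.05 there were 2 amino acids, asparagine and serine.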

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

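The alternatives in this part were planned, except summing tRNA species of one anticodon, which was chosen after seeing the data. In the footprint comparison, 0 genes were called in either direction with RLE factors, total-count scaling, no filter, DESeq2, a minimum log2 fold change of 1 or any 1 library left out. With the replicate block, 18 genes were called higher and 32 lower by edgeR, with ypfM (-1.23), pheL (-0.60), tnaC (0.37), lpp (-0.27), rplX (-0.30), hisL (-0.67) and secM (0.32 on the log2 scale) among them. The labels do not say that a number marks a shared culture or day, and with 2 pairs the check is only a hint: deviations from the group means correlated at r = 0.980 between same-numbered libraries. No gene list was called with RLE factors, total-count scaling, no filter, an estimated correlation or fry. With the replicate block, camera called 3 lists higher (central carbon metabolism, aminoacyl-tRNA synthetases, amino acid biosynthesis) and 1 lower (small hydrophobic and toxin peptides). With an estimated correlation each had an adjusted p of 0.885 (camera), as did lists not called with the block, so that setting could not decide about these calls. Leaving out 1 footprint library gave 2 to 4 lists higher and 1 to 2 lower, among RpoS-dependent stress genes, central carbon metabolism, aminoacyl-tRNA synthetases, ribosomal proteins, translation factors and protein export. RpoS-dependent stress genes were then higher without Cm replicate 2 or high-salt replicate 1 and lower without Cm replicate 1 or high-salt replicate 2, so the calls turn with the number that remains unbalanced. An estimated correlation could not decide about these calls either, because it gave most lists of one fit the same adjusted p. Of 684 alternative values of the 76 named genes, none called in the main test, 121 had the other sign. For tRNA species, where 4 were called higher and 8 lower, TMM gave 0 and 0 and RLE 0 and 0, with adjusted p from 0.0577 (TMM) and 0.0689 (RLE) for trna63-SerGCT, and DESeq2 gave 9 higher and 9 lower. Without the filter the counts stayed within 1.5 times of these. Summing by anticodon gave 5 higher and 6 lower, with other members: LeuCAG (log2 fold change -1.45, adjusted p = 0.0646) and ThrGGT (-0.43, 0.601) were not called, and LeuTAA, ThrTGT and SerTGA were. For amino acids, where 1 was called higher and 0 lower, asparagine was still called higher with TMM and with RLE, and each also gave 1 lower (serine). DESeq2 gave 2 higher (asparagine, tryptophan) and 1 lower. The cause was not tested. The 12 called species and asparagine had the same direction in every alternative run on single species or amino acids. This held with either RNC library left out too, where 1 library against 1 leaves no residual degrees of freedom and no test. It is no separate support, since only 14 of 222 alternative values of the 37 species not called had the other sign. Leaving out rows of non-translated RNAs was not run, as the files hold none. No paired analysis was possible for tRNAs because the input has 1 library. The depth of RNC replicate 1, 35593 counts, limits rare species: trna73-SerCGA rests on 17 reads there.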

Other observations

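The libraries numbered 2 differed from those numbered 1 in a broad set of genes, in Cm and after the wash alike. No test was made, because the numbers are not groups of the study, and the values below are ratios of single libraries. Of 1989 genes with a mean of at least 200 counts, 182 were at least 2-fold higher and 206 at least 2-fold lower in number 2 in both treatments. Of 23 RpoS-dependent stress genes with a mean of at least 200 counts, 19 were at least 2-fold higher in number 2 and 0 lower. wrbA, a quinone oxidoreductase gene, was 10.6-fold higher in Cm and 11.4-fold higher after the wash. dps, which encodes a DNA-protecting protein of starved cells, was 3.41-fold and 3.44-fold higher, and rpoS itself 2.80-fold and 3.18-fold higher. In central carbon metabolism 16 of 53 genes were at least 2-fold higher and 0 lower, with adhE, the fermentative alcohol dehydrogenase, at 2.61-fold and 2.66-fold. raiA, a factor that binds idle ribosomes, was 2.59-fold and 2.46-fold higher. In the other direction, 9 of 55 ribosomal protein genes were at least 2-fold lower and 1 higher. Inner membrane transporters had 11 of 58 lower and 8 higher, and cold shock proteins had 5 of 18 lower and 1 higher. rpsA was 2.25-fold and 2.49-fold higher in number 1. cspA was 4.19-fold and 4.20-fold higher in number 1, and cspE 2.98-fold and 2.70-fold.

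All the tests in the next 3 paragraphs were chosen after the result was seen. Libraries of one number resembled each other more than libraries of one group, with mean Pearson's r of 0.998 and 0.915. Depth is argued against as the cause, since with libraries thinned to 8937650 counts each the difference in r was still 0.083. An exchange of labels between Cm replicate 2 and high-salt replicate 1 stays open: the within-number ratios correlated across genes (r = 0.26, 95% bootstrap interval 0.20 to 0.33, genes not being independent), but replicates that share a culture, day or preparation would give this after an exchange too, and every wash comparison here takes the labels as given. A shared culture, day or preparation per number may account for the pattern and stays open, since the labels name none, and no biological explanation was tested.

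ORFs shorter than 50 codons had lower shares after the wash, with 10 of the 19 that had a mean of at least 200 counts lower and 3 higher in both numbers, beside 61 lower and 27 higher of 134 genes of 50 to 100 codons, 146 and 88 of 399 genes of 100 to 200, 235 and 258 of 845 genes of 200 to 400, and 147 and 208 of 592 genes of 400 codons or more, with no test between these classes. Few counts are argued against for the 19 as a set, since their median log2 ratio of -0.18 lay below the central 95% of 10000 random lists matched on mean count (-0.05 to 0.05). That set includes ypfM, hisL and pheL, which were named from genes with non-overlapping groups. The lists were not drawn without them, so the test does not decide for the other short ORFs. Whether one loss was common to all short ORFs is not decided. Their ratios correlated between the numbers (r = 0.82, rho = 0.74, n = 19, permutation p = 0.0001, the smallest that the permutations can give for r, and 3.00e-04 for rho). Without tnaC and ypfM, the 2 farthest from the median, r was 0.67 (permutation p = 0.003). Both values still include hisL and pheL, whose shared direction was fixed by the way they were named, and the correlation was not computed without them. The hypothesis that footprints of arrested ribosomes are kept through the wash stays undecided: the mean log2 ratio of tnaC and secM was 0.33 (matched pairs of genes -0.14 to 0.12), but this came mostly from number 1, at 0.53 (-0.15 to 0.13), while number 2, at 0.12 (-0.16 to 0.18), lay within the matched range. Differences in nuclease digestion or fragment selection between the washed and unwashed libraries stay open, as does RNA bound without a ribosome on ORFs such as ypfM.

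Of the 13 tRNA species with a long variable arm (leucine, serine, tyrosine and selenocysteine; 28 or more in the length column), 10 had lower shares than the input in both RNC libraries and 2, trna76-LeuTAA and trna32-SeCpTCA, had higher shares in both. The median log2 fold of the 13 was -1.29 against -0.04 for the other 36 species, and 6 of the 8 species called lower were of this class. Lower recovery of the whole class in the RNC libraries stays open: the leucine and serine species prompted the pattern, and the 3 long species of other amino acids are too few to decide (median -0.55, exact permutation p = 0.555, species not being independent replicates). Whether class alone sets the fold of every long species is not decided. trna76-LeuTAA, the highest of the 13, had a log2 fold of 1.73, but it did not pass the threshold (edgeR adjusted p = 0.0913) with 1 input library. A difference in the tRNAs that the RNC samples hold stays open, because 1 input library and the sample type cannot be separated from a difference in library preparation.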
